A study of Mus musculus with 20 samples.

How the data were processed

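Gene expression was measured in pooled RNA of liver, mesenteric white fat, brown fat, ileum and colon of mice on 4 diets, with 20 one-colour arrays in all. Per the labels, each array held RNA pooled from 7 mice of 1 tissue and 1 diet. Per the file headers, the arrays were scanned and read with Agilent Feature Extraction 11.5.1.1 under protocol GE1_1105_Oct12. The deposited scanner files hold 1 intensity per spot on a linear scale, background-subtracted and detrended within the array, and from the values no scaling between arrays had been applied.

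The series matrix deposited by the authors also holds an intensity per spot. Set against the scanner values, each of its columns was the processed signal of that array times 1 factor, exactly the same for every spot, with log2 factors between 0.916 and 1.65. The factors brought the mean of each array, trimmed by 2% at each end, to between 2498.6 and 2499.0. Its scale is linear and its values are not centred, and the labels do not state what the factor was set to. The column medians for CD, HFD, HFD+PP and HFD+Ex in that order were 54.8, 53.5, 54.3 and 54.7 in liver and 103.6, 87.9, 102.3 and 98.5 in mesenteric fat. They were 55.2, 73.6, 67.5 and 71.8 in brown fat, 96.4, 80.6, 87.1 and 91.6 in ileum, and 92.6, 84.6, 86.4 and 86.7 in colon.

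Each array had 62976 spots, of which 3671 were controls and were left out, leaving 55681 probes. Of these, 399 were printed 10 times and 33 were printed 2 times, and spots of 1 probe were averaged. Spots with an outlier flag, between 117 and 206 per array, were left out, which left 101 gene values missing in 100 genes. The share of spots well above background ran from 50.7% to 67.9%, and no spot was saturated.

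The files name probes by accession, which was matched without its version to a RefSeq gene table of assembly GRCm38.p6. A symbol was found for 28026 probes, and the 27655 without one were not used. The symbols gave 21154 genes, 5681 of them with several probes. A gene was represented by its probe with the highest mean normalized signal over the 20 arrays. Summed over comparisons, 1455 changed genes had several probes well above background on both arrays, and in 108 of them a probe went the other way.

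The log2 processed signal minus its 75th percentile on the array was used throughout. A gene was measured in a comparison when it was well above background on at least 1 of the 2 arrays, and changed when its log2 difference was at least 1 either way. Where it was not well above background on the dimmer array, the difference was taken against the floor of that array, which is the higher of the lowest signal among probes well above background and the probe's own signal. Such a difference is a bound, written "at least". Floors ran from −6.57 to −4.70 log2. Bounds were not ranked together with differences measured on both arrays.

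Within each tissue the comparisons were HFD against CD, HFD+PP against HFD, HFD+Ex against HFD, and HFD+Ex against HFD+PP. With 1 array per group no test was run and no p-value, standard error or interval is given. The spread of replicate spots within an array, times the square root of 2, gives a technical standard deviation of 0.093 log2 for a difference. It rests on 267 to 334 bright replicate probes per array. This leaves out all variation between mice and between pools.

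The genes to count, the 46 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. The text names, per tissue and comparison, the 5 highest and 5 lowest genes measured on both arrays, up to 4 members of each list with a difference of at least 1 log2, and up to 3 genes per direction with the largest bound. It also names a fixed set of genes of bile acids, lipids, ceramides, fat tissue and gut defence whatever their values. Between the supplements it names the 3 highest and 3 lowest genes, across tissues up to 10 genes, and among returned genes the 5 with the largest smaller change. Genes named outside this rule were chosen after their values were seen, which the text says. Some genes that the rule names are not reported here. Of 961 list entries 23 matched no gene on the array, and 75 of the 858 genes in lists are in several lists.

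For each list the median log2 difference was set against 10000 random lists of the same size, drawn within 20 bins of mean expression. Lists with fewer than 5 measured members were not used. Genes that changed the same way in at least 4 of the 5 tissues were counted beside the number expected from independent tissues. Genes that returned towards the control diet were compared with 100 simulations in which the 4 arrays of a tissue differ by chance only, because these comparisons share an array. Each gene was drawn with its own spread over the 4 real arrays, so any effect of the diets is part of the simulated spread. The distance between 2 arrays was 1.4826 times the median absolute deviation of the log2 differences.

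The counts and list medians were tested on simulated data for HFD minus CD in liver, run on 14966 genes with 200 of them changed. Of 67 genes with a true log2 difference of 1.5, 67 were called in the right direction, as were 65 of 65 at 3.0 and 2 of 67 at 0.8. Of 14738 unchanged genes 0 were called, and a list shifted by 0.5 gave a median of 0.52.

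The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median of probes well above background on all arrays, the authors' values, only genes well above background on both arrays, no filter on dim probes, and the mean over all probes of a gene. The mean signal column that normexp was planned for is not in the files used here, so the median signal and median background were used. Another alternative, leaving out genes typical of other tissues, was chosen after seeing the data. It drops pancreas genes and genes whose mean in another tissue lies at least 16-fold above their lowest array in the tissue compared.

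The arrays lay on 4 slides. The 4 liver arrays, with the control and high fat diet arrays of mesenteric fat, shared 1 slide, and the 4 colon arrays shared another. The other mesenteric fat arrays shared a slide with the control, high fat and porphyran arrays of brown fat, and the remaining slide held the extract array of brown fat with the 4 ileum arrays. Tools were Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, R 4.3.3 with limma 3.58.1, and matplotlib 3.10.9.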

Results

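Gene expression was measured in 5 tissues of male C57BL/6J mice on 4 diets: liver, mesenteric white fat, brown fat, ileum and colon. The diets were a control diet with 10% of energy as fat (CD), a high fat diet with 60% of energy as fat (HFD), the high fat diet with 2% by weight of porphyran (HFD+PP), and the high fat diet with 2% by weight of a nori extract (HFD+Ex). Porphyran is a sulfated polysaccharide of the red alga nori. Mice started the diets at 5 weeks of age and stayed on them for 13 weeks. Each of the 20 arrays held RNA pooled from 7 mice of 1 tissue and 1 diet, so every group was 1 array. No difference below has a replicate check, no test was possible and no p-value is given. The 5 arrays of a diet came from the same mice and are not replicates of that diet.

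On each 1-colour array, between 50.7% and 67.9% of the spots were well above background, and no spot was saturated. A gene was counted as changed when it differed by at least 2-fold between the 2 arrays compared and was well above background on at least 1 of them. "Rose" and "fell" are used for such genes only. Spots printed several times on an array differed with a median standard deviation between 0.057 and 0.076 log2, which measures the array and not the animals. The number of arrays limits the precision between diets, and 1 per group gives no estimate of it. For lists of genes, the measured members are counted and their median log2 difference is set against 10000 random lists of the same size matched on mean expression, as a description of these arrays.

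In the liver, the comparison of the high fat diet with the control diet asks what the diet itself changed. Cidea, a protein that enlarges lipid droplets, was 157-fold higher on the high fat diet, and its relative Cidec was 19.5-fold higher. Of the lipid droplet and lipid uptake genes, 7 of 20 members rose and 0 fell (median 0.50, above 10000 of 10000 random lists). Cfd, the complement protease adipsin that fat cells secrete, rose 121-fold. Cyp2b10, a drug-metabolising enzyme induced through the receptor CAR, rose 80.8-fold, and its relatives Cyp2b13 and Cyp2b9 rose at least 151-fold and at least 128-fold. Pnpla3, a phospholipase domain gene outside the lipid droplet list, fell 16.9-fold, and Fabp5, a fatty acid binding protein, fell 14.3-fold.

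Of the extracellular matrix and fibrosis genes of liver, 17 of 29 members rose and 0 fell (median 1.22, above 10000 of 10000 random lists). Timp1, an inhibitor of matrix-degrading proteases, rose 13.3-fold, and the collagen genes Col1a1 and Col3a1 rose 9.77-fold and 5.74-fold. Markers of mesothelial cells, which cover the liver surface, were also measured: 6 of 11 members rose and 0 fell. Msln rose 3.42-fold and Gpm6a 2.92-fold. Of the inflammatory mediators, 9 of 22 members rose and 0 fell (median 0.51, above 10000 of 10000 random lists, and 0.31 with normexp background correction). Ccl2, which attracts monocytes, rose 5.90-fold, and Ccl4 rose 4.98-fold. Of the macrophage markers, 8 of 25 members rose and 1 fell. Gpnmb rose at least 14.5-fold, Cx3cr1 5.30-fold and Itgax 4.85-fold. Of the acute phase genes, 7 of 23 members rose and 0 fell. Lcn2, which binds bacterial iron carriers, rose 15.5-fold, and the serum amyloid gene Saa2 rose 8.31-fold.

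Of the liver lipogenesis genes, 0 of 20 members rose and 7 fell (median −0.39, below 10000 of 10000 random lists). Fasn, which synthesises fatty acids, fell 3.43-fold, Elovl6 2.43-fold and Acaca 2.24-fold. Of the male-biased liver genes, 0 of 14 members rose and 4 fell, among them Hsd3b5, which fell 6.47-fold. In the bile acid synthesis list, 0 of 14 members rose and 1 fell. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 difference of 0.41, Cyp8b1 0.58 and Cyp7b1 −0.62. The bile salt exporter Abcc3 rose 3.10-fold. In the ceramide synthesis list, 2 of 15 members rose and 0 fell. Smpd3, a neutral sphingomyelinase that releases ceramide from sphingomyelin, rose 4.77-fold and Degs2 rose 2.29-fold, while Sptlc2 was at 0.12 log2 and Cers6 at 0.45. Of 15378 measured genes, 535 rose and 206 fell. The split became 177 higher and 53 lower with normexp background correction, 933 higher and 1151 lower with no filter on dim probes and 274 higher and 167 lower without genes typical of other tissues.

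Porphyran was added to the high fat diet to see whether it changes what that diet did. In liver, Cidea fell 11.2-fold from the high fat diet array, Cidec 3.84-fold, and Gpnmb, a marker of lipid-laden macrophages, 7.00-fold. Smpd3 fell 4.31-fold. Of the extracellular matrix genes, 0 of 29 members rose and 11 fell (median −0.82, below 10000 of 10000 random lists). Col1a1 fell 4.78-fold, Timp1 4.08-fold and Col3a1 3.39-fold, and Wt1, a mesothelial marker, 3.16-fold. The PDZ domain gene Sdcbp2 fell 14.1-fold, the asparaginase gene Asrgl1 6.87-fold and the surface protein gene Ly6d 6.72-fold.

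Of the liver macrophage markers, 0 of 25 members rose and 6 fell (median −0.25, below 9999 of 10000 random lists, and −0.10 with normexp background correction), with Trem2 down 2.72-fold and Cx3cr1 down 2.83-fold. Among the inflammatory mediators, 0 of 23 members rose and 3 fell, and the median was −0.39, or −0.25 with normexp background correction. Scd1, which desaturates fatty acids, fell 2.28-fold, while Fasn was at −0.78 log2 and Srebf1 at −0.40; of the 20 lipogenesis genes, 1 fell (median −0.39, below 10000 of 10000 random lists). Of 14 measured bile acid synthesis genes, 0 rose and 0 fell; Cyp7a1 was at 0.73 log2, Cyp7b1 at 0.54 and Nr0b2, which represses Cyp7a1, at 0.04. The cholesterol synthesis list had a median of 0.20 with no member past 2-fold. The male-biased gene Hsd3b5 rose 2.83-fold, and the retinoic acid hydroxylase gene Cyp26b1 rose 3.09-fold. Of 15373 measured genes, 89 rose and 239 fell, against 16 higher and 46 lower with normexp background correction, 32 higher and 174 lower over genes well above background on both arrays, 1041 higher and 603 lower with no filter on dim probes and 77 higher and 104 lower without genes typical of other tissues.

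With the nori extract, Cidea of liver fell 9.06-fold from the high fat diet array, Cidec 2.93-fold and Gpnmb at least 12.5-fold. Of the extracellular matrix genes, 0 of 29 members rose and 11 fell (median −0.91, below 10000 of 10000 random lists), with Col1a1 down 4.62-fold and Acta2 down 4.22-fold. Of the mesothelial markers, 0 of 11 members rose and 2 fell (median −0.51). Actg2, an actin gene, fell 8.59-fold and Cnn1, which encodes a calponin, 8.51-fold. Of the cholesterol synthesis genes, 4 of 25 members rose and 0 fell (median 0.69, above 10000 of 10000 random lists), with Sqle up 2.48-fold and Idi1 up 2.16-fold.

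Of the inflammatory mediators in liver, 0 of 23 members rose and 5 fell, with Ccl2 down 2.63-fold and Ccl7 down 3.004-fold; the list median of −0.39 became −0.12 with normexp background correction. Among the macrophage markers, 0 of 25 members rose and 7 fell. Smpd3 fell 2.09-fold, and Cyp7a1 was at 0.58 log2. The early response genes Egr2 and Atf3 fell 4.15-fold and 2.81-fold. In all, 218 genes rose and 238 fell among 14975 measured. Other settings gave 31 higher and 44 lower with normexp background correction, 71 higher and 154 lower over genes well above background on both arrays, 808 higher and 690 lower with no filter on dim probes and 195 higher and 98 lower without genes typical of other tissues. Between the supplements in liver, 211 genes were higher with the extract and 76 with porphyran. Rnf32 was 7.64-fold and Tmcc2 7.55-fold higher with the extract, while Actg2 was 4.25-fold and Cnn1 4.21-fold lower. That split became 34 higher and 5 lower with normexp background correction, 74 higher and 19 lower over genes well above background on both arrays and 571 higher and 761 lower with no filter on dim probes, and normexp moved the share of higher genes from 73.5% to 87.2%.

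**Figure D1:**
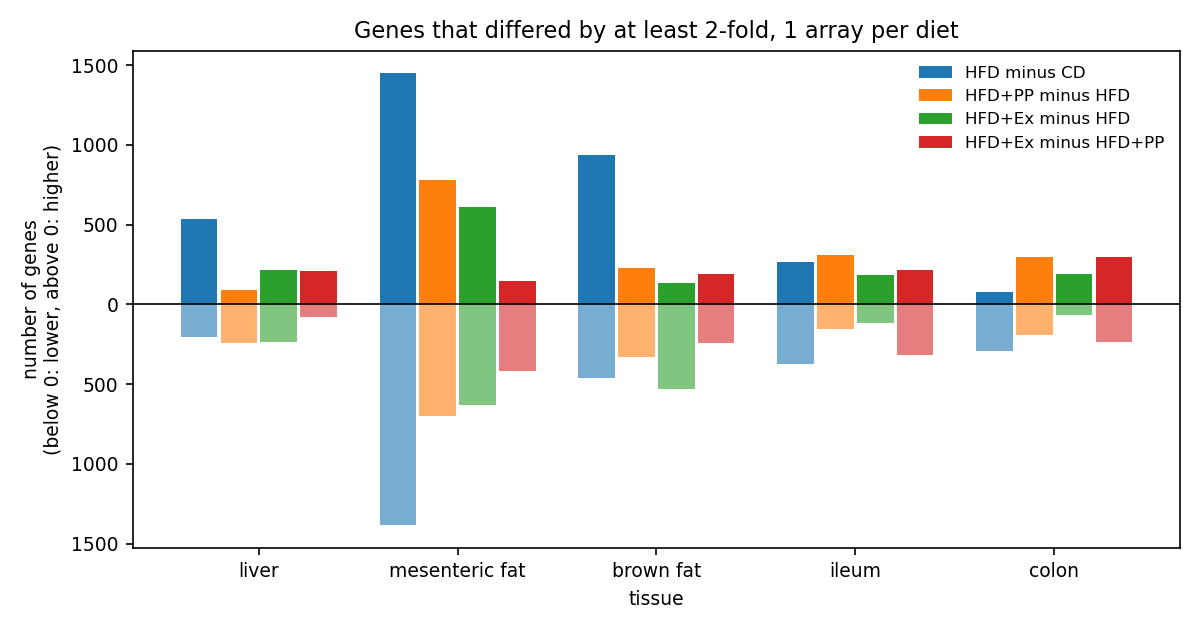
Number of genes that differed by at least 2-fold, per tissue, in 4 comparisons. Bars above 0 count genes higher on the array named before "minus" and bars below 0 count genes lower on it, with 1 array of pooled RNA per diet. The longest bars are those of mesenteric fat on the high fat diet, with 1449 genes higher and 1384 lower.

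In mesenteric white fat, the high fat diet went with more macrophage genes and fewer lymphocyte genes. Mmp12, a protease that macrophages secrete, was 57.6-fold higher, Gpnmb 25.1-fold and the lipid receptor gene Trem2 22.0-fold. Of the macrophage markers, 15 of 24 members rose and 5 fell (median 1.16, above 10000 of 10000 random lists); those lower included Marco and Timd4, markers of resident macrophages, at −3.73 and −3.74 log2. Adgre1, which encodes F4/80, rose 5.14-fold, Itgax 4.52-fold and Ccl2 7.03-fold, while Tnf fell 2.42-fold. Among the inflammatory mediators, 8 of 29 members rose and 9 fell (median −0.26, and −0.16 with normexp, −0.094 with quantile normalization and −0.145 over genes well above background on both arrays). Leptin (Lep), the hormone of fat cells, rose 7.73-fold and Mest, a gene of expanding fat cells, rose 10.00-fold, while adiponectin (Adipoq) was at 0.47 log2. Of the white adipocyte genes, 9 of 27 members rose and 1 fell (median 0.37), and of the thermogenic genes, 7 of 25 members rose and 1 fell (median 0.47).

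Of the lipogenesis genes of mesenteric fat, 0 of 19 members rose and 9 fell (median −0.94, below 10000 of 10000 random lists). Elovl6, which elongates fatty acids, fell 11.3-fold, Fasn 8.55-fold, Acaca 7.58-fold and Acly 4.62-fold. Of the extracellular matrix genes, 26 of 30 members rose and 0 fell (median 1.55, above 10000 of 10000 random lists), among them Timp1 at 5.03-fold and the collagen crosslinking enzyme gene Lox at 4.22-fold; smooth muscle genes had a median of 0.80. In the ceramide synthesis list, 1 of 16 members rose and 1 fell. Sptlc2, a subunit of the enzyme that starts ceramide synthesis, was at 0.29 log2, and Cers6 was at 0.59.

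Markers of other tissues moved on the same array. Of 20 exocrine pancreas genes, 20 fell, with a median of −5.88 log2, and Reg2 and Serpini2, which the pancreas expresses, fell 335-fold and 139-fold. Of the T cell and NK cell markers, 0 of 23 members rose and 21 fell (median −2.62, below 10000 of 10000 random lists), with Ccr7 down 15.9-fold. Of the B cell and plasma cell markers, 0 of 20 members rose and 19 fell (median −3.42, below 10000 of 10000 random lists), with Cr2 down 19.4-fold. MHC class II genes included 5 that fell of 11, led by the B cell gene H2-Eb2 at 15.2-fold. Intestinal epithelium markers rose in 13 of 15 cases, with Fabp2 up 12.2-fold, and the Paneth cell defensin gene Defa2 rose 50.6-fold. Of 16357 measured genes, 1449 rose and 1384 fell, against 908 higher and 853 lower with normexp background correction, 1312 higher and 1452 lower with scaling to bright probes, 1210 higher and 1523 lower with the authors' values and 1127 higher and 1150 lower without genes typical of other tissues.

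With porphyran, the macrophage and lymphocyte genes of mesenteric fat lay back towards the control diet array. Genes of lymph node vessels and stroma did so too, with a median of 2.22. Among the macrophage markers, 2 of 24 members rose and 12 fell (median −0.99, below 10000 of 10000 random lists). Mmp12 fell 10.3-fold from the high fat diet array, Gpnmb 9.51-fold, Trem2 8.23-fold and Itgax 4.47-fold, while Marco rose 9.02-fold. Ccl2 fell 3.44-fold, and of the inflammatory mediators, 5 of 28 members rose and 7 fell (median 0.07). Lep was at −0.65 log2, Tnf at 0.39 and Cers6 at −0.71.

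Of the T cell and NK cell markers, 15 of 23 rose, and of the B cell and plasma cell markers 16 of 20 rose, with Ccr7 up 6.36-fold. All 20 measured exocrine pancreas genes rose with them, with a median of 6.67 log2; Reg2 rose 1419-fold and Rnase1 143-fold. Of the extracellular matrix genes, 0 of 30 members rose and 4 fell (median −0.72, below 10000 of 10000 random lists), with Timp1 down 3.69-fold, and smooth muscle genes had a median of −0.79. The lipogenesis list had a median of −0.11 and 0 members that rose. Of the thermogenic genes, 1 of 25 members rose and 2 fell (median −0.16): Ucp1, the uncoupling protein of brown fat, rose 6.74-fold. Pck1, which makes glycerol phosphate in fat cells, rose 2.19-fold. The counts were 782 genes higher and 700 lower among 16670, and 417 higher and 262 lower with normexp background correction, 690 higher and 831 lower with quantile normalization, 1386 higher and 969 lower with no filter on dim probes and 551 higher and 598 lower without genes typical of other tissues. These arrays lay on different slides, so the slide and the diet cannot be told apart here.

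With the extract, of the macrophage markers of mesenteric fat, 2 of 24 members rose and 11 fell (median −0.85, below 10000 of 10000 random lists), with Mmp12 down 8.18-fold and Trem2 down 7.35-fold. Of the B cell and plasma cell markers, 16 of 20 members rose and 0 fell, and exocrine pancreas genes rose in 20 of 20 cases with a median of 4.87. Of the intestinal epithelium markers, 0 of 15 members rose and 13 fell (median −3.09, below 10000 of 10000 random lists): the goblet cell gene Tff3 fell 28.0-fold, the apolipoprotein gene Apoa4 44.4-fold and the alkaline phosphatase gene Alpi 28.1-fold. In the list of inflammatory mediators, 6 of 26 members rose and 4 fell (median 0.18, and 0.077 with normexp, 0.074 with quantile normalization and 0.065 with no filter). The cytokine genes Il1b and Il6 rose 5.77-fold and 4.99-fold, and S100a9, a neutrophil protein, rose 5.27-fold.

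Thermogenic genes in mesenteric fat had a median of −0.39 with the extract, and 5 of 25 fell, led by Slc27a2 at 5.41-fold. Ccl2 fell 2.14-fold and Itgax 3.999-fold, while Lep was at −0.98 log2 and Sptlc2 at −0.39. Of 16643 genes, 612 rose and 628 fell; other settings gave 323 higher and 330 lower with normexp background correction, 626 higher and 614 lower with scaling to bright probes, 683 higher and 562 lower with the authors' values, 489 higher and 464 lower over genes well above background on both arrays, 1169 higher and 1002 lower with no filter on dim probes and 502 higher and 323 lower without genes typical of other tissues. The extract and porphyran arrays of this fat shared a slide, and 148 genes were higher and 414 lower with the extract. Il12a was 9.90-fold and Il6 6.37-fold higher, and Defa40, Defa27 and Defa23, defensins of Paneth cells, were 115-fold, 102-fold and 97.1-fold lower. The split was 10 higher and 230 lower with normexp background correction, 45 higher and 298 lower over genes well above background on both arrays, 434 higher and 855 lower with no filter on dim probes and 132 higher and 82 lower without genes typical of other tissues, and the share of higher genes was 26.3% against 4.17% with normexp.

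**Figure D2:**
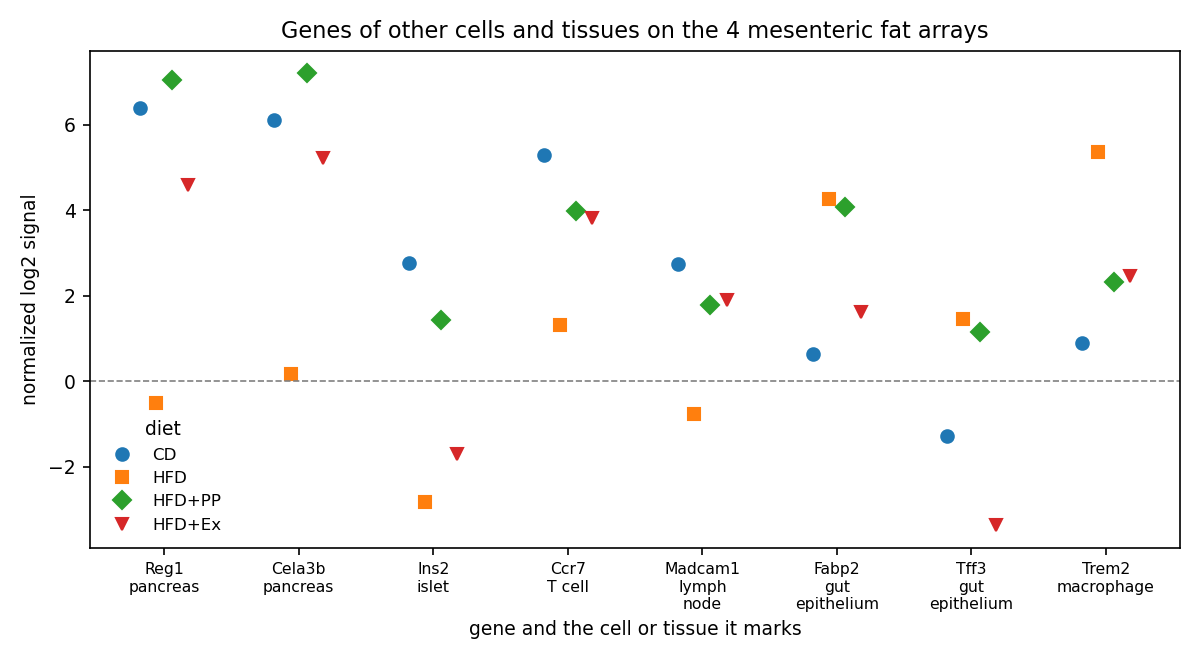
Normalized log2 signal of 8 genes of other cells or tissues, picked after their values were seen, on the 4 mesenteric fat arrays, 1 array of pooled RNA per diet and point. The dashed line marks 0, the 75th percentile of each array. The lymphocyte gene Ccr7 lies 15.9-fold lower on the high fat diet than on the control diet array, and Trem2 lies 22.0-fold higher.

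In brown fat, the high fat diet went with more macrophage genes and fewer lipogenesis genes. Of the macrophage markers, 19 of 24 members rose and 0 fell (median 1.59, above 10000 of 10000 random lists, and 1.04 with normexp background correction). Atp6v0d2 rose at least 21.2-fold, Gpnmb 10.8-fold, Itgax 10.3-fold and Trem2 10.2-fold. Among the inflammatory mediators, 9 of 19 members rose and 0 fell (median 0.87, and 0.42 with normexp), with Ccl2 up 5.74-fold. Of the lipogenesis genes, 0 of 18 members rose and 11 fell (median −1.14, below 10000 of 10000 random lists), among them Scd2, which fell 3.35-fold, and Elovl6, which fell 3.10-fold. Leptin rose 4.58-fold.

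Of the thermogenic genes of brown fat, 0 of 26 members rose and 1 fell, and Elovl3, which elongates fatty acids, fell 2.997-fold. Ucp1 was at −0.18 log2, Dio2, which activates thyroid hormone, at 0.34, Ppargc1a at −0.50 and Cidea at −0.41. The list median of −0.30 became −0.06 with quantile normalization and −0.02 with the authors' values. The fatty acid oxidation list had a median of −0.33, which turned to 0.03 with quantile normalization. Respiratory chain genes had a median of −0.48, with no member past 2-fold. On the same array, of the hepatocyte markers, 11 of 20 members rose and 1 fell (median 1.74, above 10000 of 10000 random lists), and Mup20, a major urinary protein gene of liver, rose 17.8-fold, Fabp1 14.1-fold and Gc 11.9-fold. Of 14955 measured genes, 936 rose and 461 fell. Other settings gave 305 higher and 158 lower with normexp background correction, 567 higher and 289 lower over genes well above background on both arrays and 1618 higher and 792 lower with no filter on dim probes. The share of higher genes was 67.0%, and 84.7% with the authors' values.

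With porphyran, of the macrophage markers of brown fat, 0 of 24 members rose and 4 fell (median −0.49, below 10000 of 10000 random lists), with Vsig4 down at least 3.01-fold and Itgax down 2.01-fold. Of the hepatocyte markers, 1 of 20 members rose and 12 fell (median −1.65), with Alb, which encodes albumin, down 16.6-fold and Mup20 down 39.2-fold. Of the skeletal muscle genes, 8 of 20 members rose and 0 fell (median 0.95, above 10000 of 10000 random lists); Myh2, a myosin of fast muscle fibres, rose 4.25-fold. Cyp2b10 rose 5.37-fold and the carboxylesterase gene Ces1e 5.12-fold.

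Thermogenic genes of brown fat had a median of 0.23 with porphyran and respiratory chain genes 0.13, with no member of either past 2-fold. Ucp1 was at 0.02 log2 and Lep at −0.96. Scd2 fell 2.08-fold and Smpd3 2.06-fold. The MHC class II median was −0.57, and −0.29 with normexp. Of 15109 measured genes, 230 rose and 329 fell, against 33 higher and 75 lower with normexp background correction, 97 higher and 138 lower over genes well above background on both arrays, 547 higher and 1171 lower with no filter on dim probes and 198 higher and 179 lower without genes typical of other tissues.

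With the extract, of the macrophage markers of brown fat, 0 of 25 members rose and 12 fell (median −0.92, below 10000 of 10000 random lists). Trem2 fell 3.59-fold, Atp6v0d2 4.17-fold and Spp1, which encodes osteopontin, 3.52-fold. Of the inflammatory mediators, 0 of 21 members rose and 7 fell (median −0.56, and −0.33 with normexp), with Ccl2 down 3.41-fold. Hepatocyte markers fell in 11 of 20 cases, with Apoh down 6.29-fold, and Mup5 fell 9.80-fold. Csrp3, a muscle LIM protein, rose 9.08-fold.

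The thermogenic list of brown fat had a median of 0.27 with the extract, the respiratory chain list 0.29 and the list of fatty acid oxidation genes 0.32, or 0.17 with quantile normalization. The thermogenic median became 0.13 with quantile normalization and 0.165 with the authors' values. Ucp1 was at 0.36 log2 and Dio2 at −0.34. Of 15965 measured genes, 135 rose and 532 fell; 17 higher and 127 lower with normexp background correction, 50 higher and 365 lower over genes well above background on both arrays, 1130 higher and 835 lower with no filter on dim probes and 112 higher and 313 lower without genes typical of other tissues. This array was on another slide than the other 3 of its tissue, so slide and diet cannot be told apart. Against porphyran, 194 genes were higher and 244 lower with the extract, with Sim2 at 10.3-fold, Pifo at 6.06-fold and Ces1e lower at 6.54-fold. Those counts were 20 higher and 27 lower with normexp background correction, 51 higher and 89 lower over genes well above background on both arrays and 1661 higher and 486 lower with no filter on dim probes, and quantile normalization moved the share of higher genes from 44.3% to 25.3%.

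**Figure D3:**
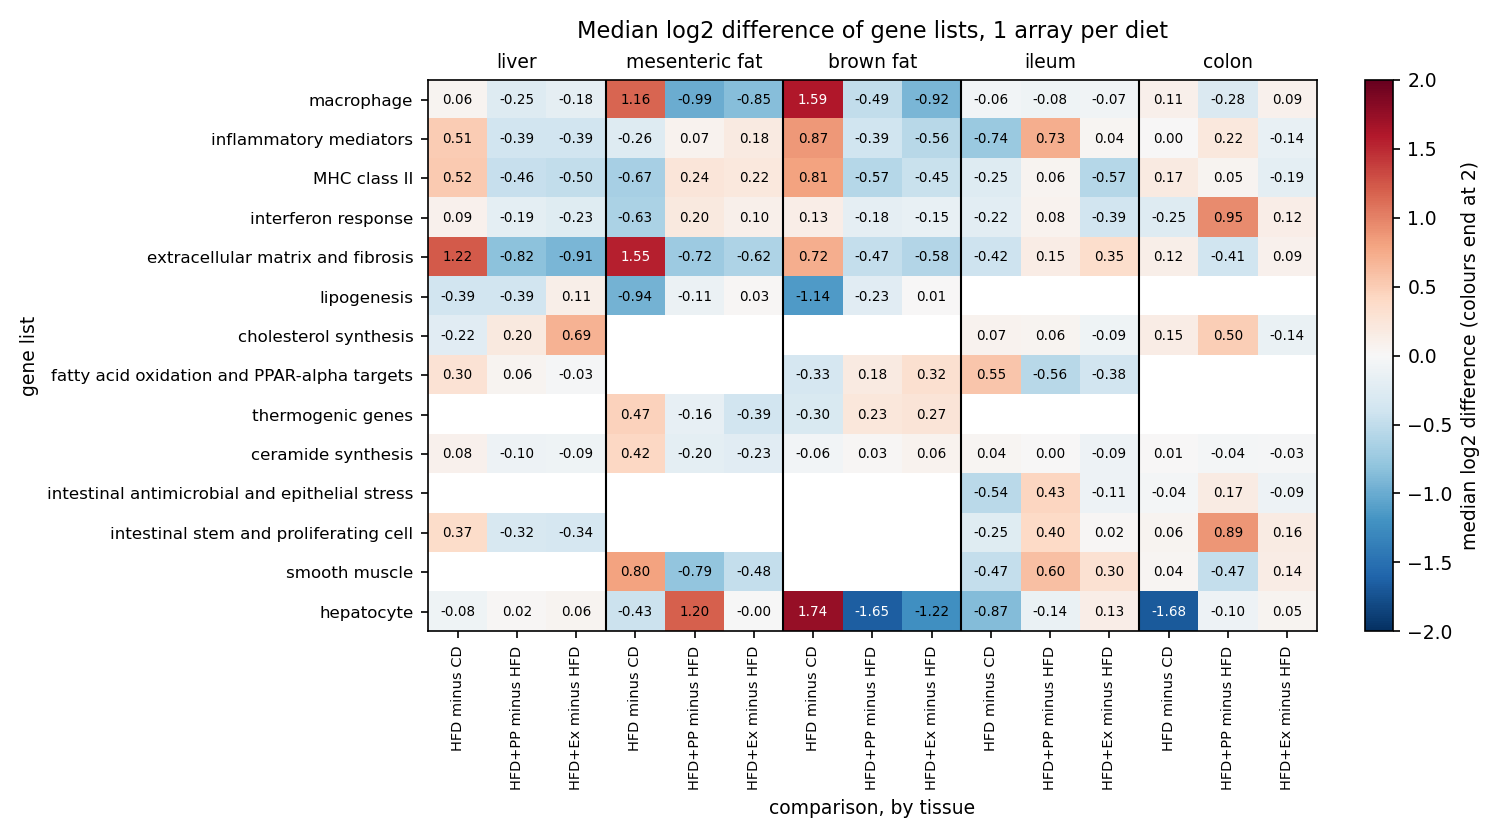
Median log2 difference of 14 gene lists in 5 tissues and 3 comparisons, 1 array per diet. Red cells are higher and blue cells lower on the array named before "minus", colours end at 2 log2 either way, and blank cells mark lists not used in that tissue or with fewer than 5 measured members. The macrophage list reads 1.16 in mesenteric fat and 1.59 in brown fat on the high fat diet, and −0.99 and −0.49 with porphyran.

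In the ileum, Fgf15, the hormone that bile acids induce there through the receptor FXR, rose 4.07-fold on the high fat diet, and the bile acid exporter Abcc2 rose 3.25-fold. The fatty acid binding protein gene Fabp1 rose 8.43-fold, Apoa4 6.46-fold and Lct, which encodes lactase, 6.57-fold. The cytochrome P450 genes Cyp1a1 and Cyp2c55 rose 9.14-fold and 9.11-fold, and of the xenobiotic metabolism genes, 7 of 20 members rose and 0 fell (median 0.35, above 10000 of 10000 random lists). Retnlb, an antibacterial protein of goblet cells, fell 8.01-fold, and the cytokine gene Il22 fell 4.95-fold.

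Of the FXR targets and bile acid transporters of ileum, 2 of 12 members rose and 0 fell (median 0.29, above 9953 of 10000 random lists, 0.16 with quantile normalization and 0.19 with the authors' values); the bile acid importer Slc10a2 was at 0.30 log2 and the binding protein Fabp6 at 0.18. Of the lipid absorption genes, 3 of 26 members rose and 0 fell (median 0.66, above 10000 of 10000 random lists). Of the antimicrobial and epithelial stress genes, 0 of 27 members rose and 10 fell (median −0.54, below 10000 of 10000 random lists), and S100a9 fell 5.98-fold, while Reg3g, an antibacterial lectin, was at −0.10. Of the inflammatory mediators, 0 of 26 members rose and 9 fell (median −0.74, and −0.44 with normexp background correction).

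Cell markers of ileum moved with these lists: smooth muscle genes had a median of −0.47, endothelial genes −0.39 and enterocyte genes 0.50. Of the hepatocyte markers, 1 of 20 members rose and 9 fell (median −0.87), with Alb down at least 97.1-fold, and of the acute phase genes, most of which liver makes, 13 of 21 fell. Sptlc2 was at −0.06 log2, Cers6 at 0.47 and Smpd3 at −0.09. Of 16512 measured genes, 267 rose and 376 fell. Other settings gave 145 higher and 87 lower with normexp background correction, 349 higher and 271 lower with quantile normalization, 221 higher and 199 lower over genes well above background on both arrays, 494 higher and 1277 lower with no filter on dim probes and 197 higher and 227 lower without genes typical of other tissues. The share of higher genes was 41.5%, against 62.5% with normexp, 56.3% with quantile normalization and 29.7% with the authors' values.

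With porphyran, Cyp2c55 of ileum fell 26.7-fold from the high fat diet array, Fabp1 12.4-fold, Cyp1a1 7.94-fold, Abcc2 2.505-fold and Fgf15 2.16-fold. Abcg5, a sterol exporter, fell 3.47-fold. Retnlb rose 3.75-fold, S100a8 3.90-fold and Il17a, the cytokine of T helper 17 cells, 3.08-fold.

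Of the xenobiotic metabolism genes of ileum, 0 of 20 members rose and 7 fell (median −0.30, below 9999 of 10000 random lists), and of the antimicrobial and epithelial stress genes, 7 of 26 members rose and 0 fell (median 0.43, above 10000 of 10000 random lists). Lipid absorption genes had a median of −0.48, with 3 of 26 lower. Of the inflammatory mediators, 6 of 26 members rose and 0 fell (median 0.73, and 0.36 with normexp). Of the FXR targets and bile acid transporters, 0 of 11 members rose and 2 fell. Smooth muscle genes had a median of 0.60 on the same array, enterocyte genes −0.42 and proliferation genes 0.40. Slc10a2 was at −0.22 log2 and Fabp6 at −0.10. Of 15981 measured genes, 312 rose and 152 fell, against 66 higher and 70 lower with normexp background correction, 142 higher and 114 lower over genes well above background on both arrays and 677 higher and 530 lower with no filter on dim probes; normexp moved the share of higher genes from 67.2% to 48.5%.

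With the extract, Cyp1a1 of ileum fell 8.77-fold, Fabp1 8.42-fold and Cyp2c55 3.96-fold, while Fgf15 was at −0.84 log2. Retnlb, which rose with porphyran, fell 3.97-fold with the extract. Nr0b2, a repressor that FXR induces, rose at least 2.23-fold. The MHC class II genes had a median of −0.57, the B cell and plasma cell markers −0.48, the T cell and NK cell markers −0.39 and the interferon response genes −0.39, each below 10000 of 10000 random lists. The macrophage markers were at −0.065 and those of mast cells and granulocytes at −0.003.

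Of the xenobiotic metabolism genes of ileum, 0 of 20 members rose and 4 fell with the extract. Enterocyte genes had a median of −0.26, below 10000 of 10000 random lists. Of the antimicrobial and epithelial stress genes, 0 of 26 members rose and 3 fell, and of the FXR targets and bile acid transporters, 1 of 12 members rose and 0 fell. Respiratory chain genes had a median of −0.23 and smooth muscle genes 0.30, with no member past 2-fold. The Paneth cell list had a median of 0.31, and its lipase gene Pnliprp2 rose 2.02-fold. Among 16259 measured genes, 186 rose and 114 fell; 35 higher and 42 lower with normexp background correction, 81 higher and 70 lower over genes well above background on both arrays and 698 higher and 477 lower with no filter on dim probes. The share of higher genes was 62.0%, and 45.5% with normexp. Compared with porphyran, the extract array had 217 genes higher and 318 lower: Cyp2c55 was 6.75-fold higher and Retnlb 14.9-fold lower. The split was 78 higher and 98 lower with normexp background correction, 139 higher and 155 lower over genes well above background on both arrays and 713 higher and 632 lower with no filter on dim probes.

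In the colon, Reg3b, an antibacterial lectin, fell 8.46-fold on the high fat diet and its relative Reg3g 2.12-fold, while Retnlb was at −0.71 log2. Of the antimicrobial and epithelial stress genes, 1 of 25 members rose and 2 fell (median −0.04). The bile acid importer Slc10a2 fell 2.60-fold. Creb3l3, a transcription factor of lipid metabolism, rose 6.68-fold, and the mast cell protease genes Cpa3 and Mcpt4 rose 4.02-fold and 2.49-fold. Slc9a3, the sodium and proton exchanger of the gut surface, and the intestinal transcription factor gene Isx fell 22.0-fold and 9.18-fold.

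On the same array Mup20 fell 65.7-fold and Alb 23.2-fold, and of the hepatocyte markers, 0 of 20 members rose and 11 fell (median −1.68, below 10000 of 10000 random lists). Of the acute phase genes, most of which liver makes, 1 of 23 members rose and 9 fell. Interferon response genes had a median of −0.25 and enterocyte and colonocyte genes −0.19. Gcg, which encodes the precursor of GLP-1, was at −0.40 log2, Pyy at 0.03, Gpbar1, a bile acid receptor, at −0.18, and the tight junction genes Tjp1 and Ocln at 0.07 and 0.11. Of 17097 measured genes, 77 rose and 291 fell, against 15 higher and 103 lower with normexp background correction, 41 higher and 176 lower over genes well above background on both arrays, 374 higher and 886 lower with no filter on dim probes and 62 higher and 114 lower without genes typical of other tissues.

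With porphyran, Reg3b of colon rose 32.9-fold from the high fat diet array, Reg3g 9.72-fold and Retnlb 6.36-fold. Of the antimicrobial and epithelial stress genes, 3 of 25 members rose and 0 fell (median 0.17). Slc9a3 rose 45.8-fold and Isx 22.9-fold. Of the interferon response genes, 14 of 29 members rose and 0 fell (median 0.95, above 10000 of 10000 random lists); the chemokine gene Cxcl10 rose 4.33-fold, Igtp, a GTPase that interferon gamma induces, 3.44-fold, and Ifng itself at least 4.04-fold. Of the stem and proliferating cell genes, 8 of 24 members rose and 0 fell (median 0.89, above 10000 of 10000 random lists), with Mcm5 up 2.19-fold and Rrm2 up 2.16-fold.

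Cholesterol synthesis genes of colon had a median of 0.50 with porphyran. The bile acid exporters Slc51a and Slc51b rose 2.54-fold and 2.45-fold. Alpi rose 5.11-fold, Fabp2 5.14-fold and the peptide hormone gene Guca2a 2.70-fold, while Klk15, a kallikrein protease, fell 7.35-fold and Creb3l3 5.05-fold. Markers of other cells moved with these genes: smooth muscle had a median of −0.47, endothelial cells −0.27 and extracellular matrix −0.41, and 8 of 20 exocrine pancreas genes rose, with Amy2a5 up 9.87-fold. Hoxd10, Hoxd11 and Hoxd12, transcription factors of the distal gut picked after their values were seen, were at −2.29, −2.26 and −2.27 log2. Gcg was at 0.77 log2, Pyy at 0.33 and Ocln at −0.27. Of 16976 measured genes, 295 rose and 189 fell. The split became 91 higher and 48 lower with normexp background correction and 777 higher and 590 lower with no filter on dim probes.

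In the colon, the extract array had fewer genes past 2-fold. Reg3b rose 3.75-fold and Slc9a3 5.49-fold, while Reg3g was at 0.36 log2 and Retnlb at −0.75. Of the antimicrobial and epithelial stress genes, 1 of 25 members rose and 3 fell. Cyp1a1, an enzyme induced through the aryl hydrocarbon receptor, rose at least 7.28-fold, and Ahrr, a repressor of that receptor, 2.09-fold. The neutrophil gene S100a8 fell 3.73-fold and haptoglobin (Hp) 4.35-fold. Of the exocrine pancreas genes, 8 of 20 members rose and 0 fell, with Amy2a5, a pancreatic amylase, up 11.54-fold.

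B cell and plasma cell genes of colon had a median of −0.32 with the extract and MHC class II genes −0.19, with no member past 2-fold. Of 16909 measured genes, 193 rose and 67 fell, against 15 higher and 7 lower with normexp background correction, 66 higher and 37 lower over genes well above background on both arrays and 544 higher and 462 lower with no filter on dim probes. Against porphyran, 297 genes were higher and 234 lower with the extract. Isx was 16.9-fold lower, Apol10a 10.9-fold and Retnlb 10.7-fold, and Gpnmb was 6.24-fold higher. Other settings gave 54 higher and 84 lower with normexp background correction, 174 higher and 169 lower over genes well above background on both arrays and 670 higher and 713 lower with no filter on dim probes, and the share of higher genes was 55.9%, or 39.1% with normexp.

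**Figure D4:**
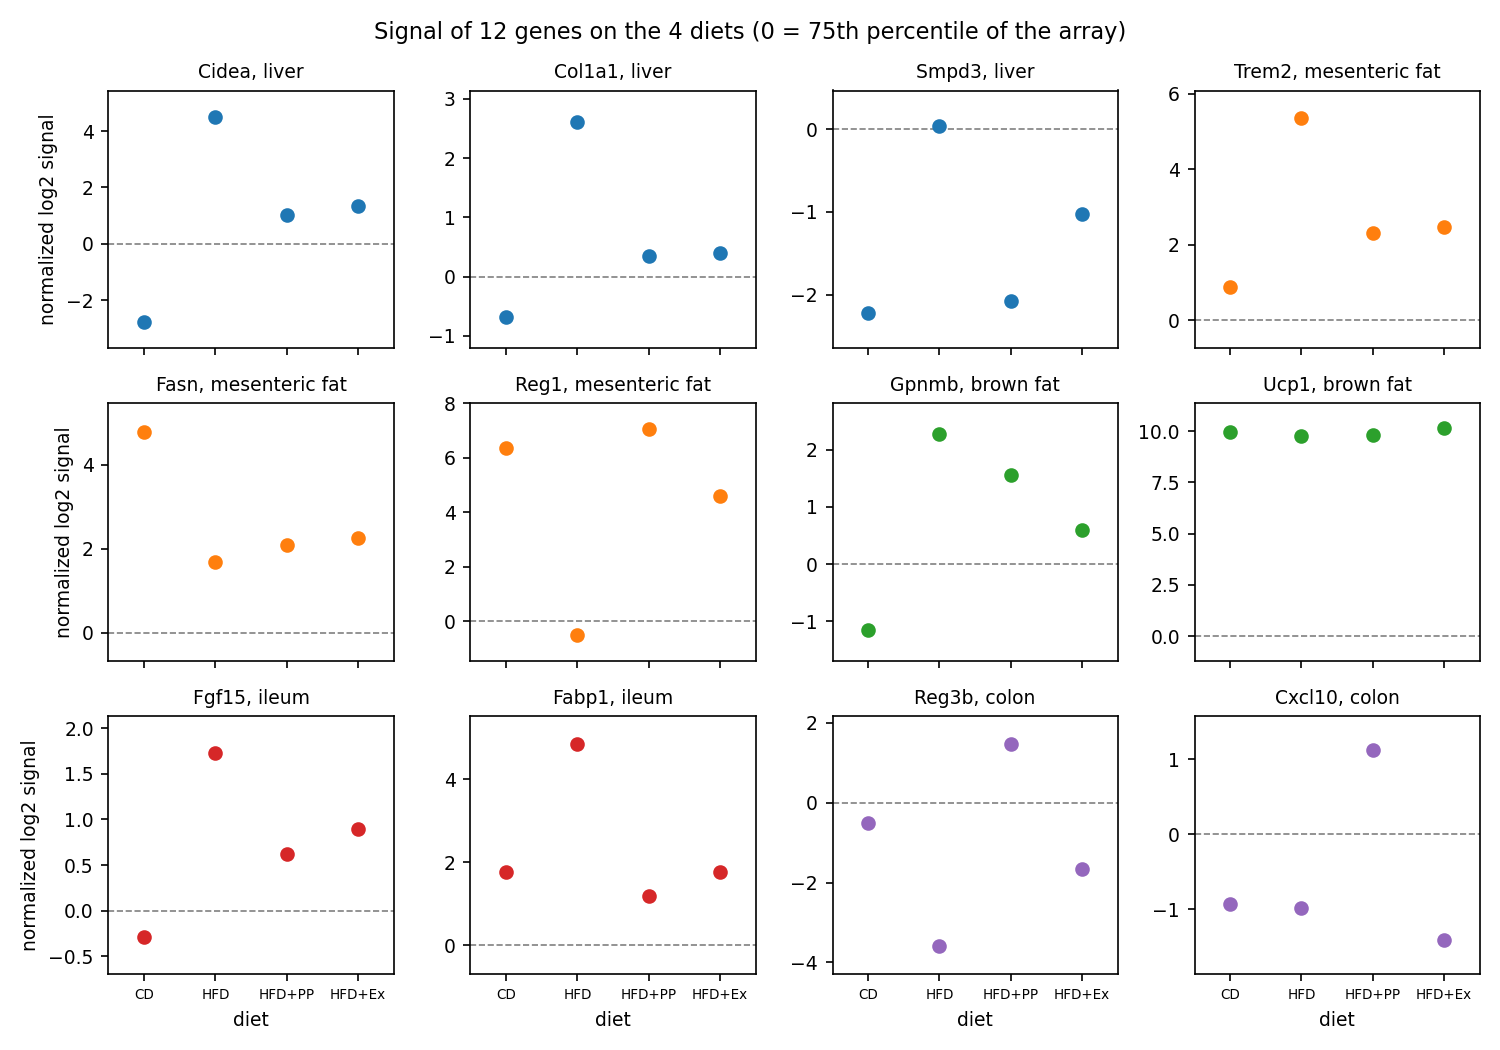
Normalized log2 signal of 12 genes, picked after their values were seen, on the 4 diet arrays of the tissue given in each panel, 1 array of RNA pooled from 7 mice per point. Dashed lines mark 0, the 75th percentile of each array. Cidea in liver was 157-fold higher on the high fat diet than on the control diet, and Reg3b in colon was 32.9-fold higher with porphyran than on the high fat diet.

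On the high fat diet, 9 genes rose in at least 4 of the 5 tissues, against 0.016 for independent tissues, which those of the same mice are not. That count was 0 with normexp and 4 over genes well above background on both arrays. The 9 were the macrophage and lysosome genes Gpnmb, Trem2, Mmp12 and Atp6v0d2, and Cyp2b10, Atp1a4, Creb3l3, Ccn5 and Lamb3. Gpnmb had the largest median, at 10.8-fold. Cyp2e1, Scd3, Fasn and Scd1 fell in at least 4, with medians of −2.23, −1.73, −1.60 and −1.14 log2. Cyp2e1 and Creb3l3 were at 0.06 and 0.04 in liver. With porphyran, Atp1a4 and Creb3l3 fell in at least 4, and with the extract Gpnmb, Ubd, Mmp12 and S100g did. With normexp these were 0 and 2. No gene rose in 4 tissues with either supplement or changed in 4 between them. Genes of other tissues, higher on some arrays, were not left out.

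The genes changed by the high fat diet were then followed in the supplement arrays. In liver, 227 of 706 genes (32.2%) that the high fat diet changed went the other way by at least 2-fold with porphyran, and 204 of 683 (29.9%) with the extract. Among them were Cidea, Gpnmb and Sdcbp2. In mesenteric fat, 1060 of 2747 genes (38.6%) did so with porphyran and 1040 of 2746 (37.9%) with the extract, led by pancreas genes such as Reg2. In brown fat the counts were 267 of 1260 (21.2%) and 427 of 1282 (33.3%), with liver genes such as Fgg and Mup20 among them for porphyran. In ileum they were 200 of 492 (40.65%) and 75 of 526 (14.3%), with Fabp1 in both, and in colon 104 of 297 (35.0%) and 59 of 278 (21.2%), with Slc9a3 in both. With normexp background correction the porphyran counts became 46 in liver, 572 in mesenteric fat, 54 in brown fat, 88 in ileum and 30 in colon, and those of the extract 42, 589, 118, 18 and 10.

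Each such pair of comparisons shares the high fat diet array, so chance in that array alone gives opposite differences. In simulations in which the 4 arrays of a tissue differed by chance only, 34.6% of the changed genes of liver returned with porphyran, 40.8% in mesenteric fat, 37.6% in brown fat, 35.5% in ileum and 36.7% in colon. For independent lists the porphyran overlaps would be 9.20, 121, 23.2, 5.23 and 4.23 genes in that order. For the extract the simulated shares were 34.7%, 40.9%, 37.5%, 35.4% and 37.0%, and the overlaps of independent lists 9.52, 102.8, 35.1, 3.78 and 1.44 genes. The observed share was below the simulated share in each tissue and supplement except ileum with porphyran. The simulated spread of each gene was its spread over the 4 real arrays, which includes any effect of the diets. Simulated changed genes for porphyran numbered 365 against 706 observed in liver and 1230 against 2747 in mesenteric fat, but 368 against 297 in colon. A share below the simulated share thus does not show that genes returned by chance alone. Part of the excess over independent lists may come from the shared array.

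Covariances across genes, which are not independent replicates, had the simulated covariance subtracted. Since the simulation used the spread of the real arrays, the part subtracted may hold an effect of the diets. For the high fat diet against porphyran the remaining covariance was −0.049 in liver, −0.328 in mesenteric fat, −0.051 in brown fat, −0.052 in ileum and 0.025 in colon. For the extract it was −0.042, −0.309, −0.082, 0.004 and 0.047. The correlations across genes with porphyran were −0.70, −0.81, −0.61, −0.72 and −0.33, against simulated values between −0.50 and −0.51.

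Porphyran and the extract changed 165 of 288 genes (57.3%) alike in liver, 904 of 1446 (62.5%) in mesenteric fat, 274 of 465 (58.9%) in brown fat, 70 of 327 (21.4%) in ileum and 55 of 422 (13.0%) in colon. The simulated shares were 34.8%, 40.8%, 37.2%, 35.6% and 36.3%, and independent lists would share 4.14, 53.7, 12.3, 2.15 and 2.04 genes. The covariance left after subtraction was 0.017, 0.160, 0.034, −0.017 and −0.042 in the same order. The simulation took the 4 arrays as independent, with the spread of each gene over the real arrays. In mesenteric fat both supplement arrays lay on another slide than the high fat diet array, so any slide effect would move both alike and is part of these values.

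The distance between 2 arrays of a tissue was taken as the robust standard deviation of the log2 differences over genes bright on all 4 arrays. In liver, mesenteric fat and brown fat, the porphyran and extract arrays were the closest pair, at 0.128, 0.124 and 0.146 log2, and the control and high fat diet arrays the farthest, at 0.267, 0.570 and 0.377. In ileum the closest pair was control diet and porphyran, at 0.153, and in colon high fat diet and extract, at 0.118. The porphyran array of colon was the farthest from the other 3, at 0.245 from the control diet, 0.233 from the high fat diet and 0.256 from the extract.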

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

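Gene lists and lists of cell type markers were picked out whose median lay at least 0.5 log2 from 0, and apart from random lists, in opposite directions in 2 tissues under the same comparison. Each value rests on 1 array per diet and tissue, and the differences between tissues were not tested.

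On the high fat diet, the inflammatory mediators had a median of 0.87 in brown fat and −0.74 in ileum, a difference of 1.61 log2. With normexp background correction these medians were 0.42 and −0.44, under the size asked for. The acute phase genes had a median of 0.55 in mesenteric fat and −1.21 in ileum, 1.76 apart. The MHC class II genes had a median of 0.81 in brown fat and −0.67 in mesenteric fat, 1.477 apart, and the B cell and plasma cell markers 0.53 and −3.42, 3.95 apart. Hepatocyte markers were at 1.74 in brown fat and −1.68 in colon, 3.42 apart. With porphyran, hepatocyte markers were at 1.20 in mesenteric fat and −1.65 in brown fat, 2.85 apart, smooth muscle genes at 0.60 in ileum and −0.79 in mesenteric fat, 1.39 apart, and mesothelial markers at 0.63 in ileum and −0.53 in liver, 1.16 apart. For the extract against porphyran, hepatocyte markers were at 0.90 in brown fat and −0.82 in mesenteric fat, 1.72 apart. Liver makes most acute phase proteins, and liver genes were also higher on the control diet array of ileum, for which tests are given among the other observations. No biological explanation of these differences was tested.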

How the results depend on the processing

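Nothing here was tested, so values are compared by size. A shift of 0.093 log2, taken from the spread of replicate spots within an array, served as a mark of size for medians, correlations and distances. It does not measure the spread of a median or a correlation. For counts the mark was 1.5 times. The alternative without genes of other tissues was chosen after seeing the data and applies to the counts of changed genes. Of the counts of changed genes, 98 values stayed within that mark and 62 moved past it. Of 798 values for 114 list medians, 713 shifted by less than the mark, 85 by more, and 39 changed sign. No sign change was in a list that stood apart from random lists, and the largest median among them was the −0.33 of fatty acid oxidation genes in brown fat. For 368 named differences of at least 2-fold, 2543 values changed sign in 0 cases. Scaling to the median of bright probes moved none of the counts or list medians past these marks. The cause was not tested for any change below except where the construction of the setting is named.

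The authors' values shifted the median of all genes by 0.28 log2 for the high fat diet in brown fat and by −0.10 in ileum, and quantile normalization shifted it by 0.13 in brown fat. Because the authors' factor is 1 number per array, each list median of a comparison shifts with it by the same amount.

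Normexp background correction, which leaves dim probes closer together, moved all 20 totals of genes changed 2-fold. Listed for the high fat diet, porphyran, the extract and extract against porphyran, the totals became 230, 62, 75 and 39 in liver and 1761, 679, 653 and 240 in mesenteric fat. They were 463, 108, 144 and 47 in brown fat, 232, 136, 77 and 176 in ileum and 118, 139, 22 and 138 in colon. In at least 4 tissues it gave 0 higher for the high fat diet (from 9), 0 lower for porphyran (from 2) and 2 lower for the extract (from 4). In liver, mesenteric fat, brown fat, ileum and colon in that order, returned genes numbered 46, 572, 54, 88 and 30 with porphyran. With the extract they were 42, 589, 118, 18 and 10, and genes changed alike 33, 477, 62, 19 and 10. The distance between control and high fat diet arrays became 0.460 in mesenteric fat and 0.279 in brown fat. Across genes, the correlation became 0.209 for both supplements in colon (from 0.305).

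List medians moved under normexp as follows, most of them towards 0. The FXR target and bile acid transport median became −0.11 for the high fat diet in colon (from −0.23). The ceramide synthesis median became 0.28 for the high fat diet in mesenteric fat (from 0.42). The lipogenesis median became −0.079 for the extract in mesenteric fat (from 0.026). The thermogenic median became 0.35 for the high fat diet in mesenteric fat (from 0.47). The white adipocyte median became −0.20 for the high fat diet in brown fat (from −0.29). The macrophage median became −0.10 for porphyran in liver (from −0.25), −0.75 for the extract in mesenteric fat (from −0.85), 1.04 for the high fat diet in brown fat (from 1.59), −0.74 for the extract in brown fat (from −0.92) and −0.16 for porphyran in colon (from −0.28). The inflammatory mediator median became 0.31 for the high fat diet in liver (from 0.51), −0.25 for porphyran in liver (from −0.39), −0.12 for the extract in liver (from −0.39), −0.15 for the high fat diet in mesenteric fat (from −0.26), 0.077 for the extract in mesenteric fat (from 0.18), 0.42 for the high fat diet in brown fat (from 0.87), −0.33 for the extract in brown fat (from −0.56), −0.44 for the high fat diet in ileum (from −0.74) and 0.36 for porphyran in ileum (from 0.73). The MHC class II median became 0.36 for the high fat diet in liver (from 0.52), −0.30 for the extract in liver (from −0.50), −0.29 for porphyran in brown fat (from −0.57) and −0.45 for the extract in ileum (from −0.57).

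With quantile normalization over the 20 arrays, these list medians moved. The FXR target and bile acid transport median became 0.16 for the high fat diet in ileum (from 0.29). The ceramide synthesis median became 0.058 for the high fat diet in brown fat (from −0.062). The lipogenesis median became −0.77 for the high fat diet in brown fat (from −1.14) and −0.13 for the extract in brown fat (from 0.010). The cholesterol synthesis median became 0.59 for the extract in liver (from 0.69). The fatty acid oxidation median became −0.040 for porphyran in liver (from 0.057), 0.034 for the high fat diet in brown fat (from −0.33) and 0.17 for the extract in brown fat (from 0.32). The thermogenic median became −0.061 for the high fat diet in brown fat (from −0.30) and 0.13 for the extract in brown fat (from 0.27). The white adipocyte median became 0.038 for porphyran in mesenteric fat (from 0.13), 0.11 for the high fat diet in brown fat (from −0.29) and 0.028 for the extract in brown fat (from 0.16). The macrophage median became −1.06 for the extract in brown fat (from −0.92). The inflammatory mediator median became −0.094 for the high fat diet in mesenteric fat (from −0.26), 0.074 for the extract in mesenteric fat (from 0.18) and 0.10 for the high fat diet in colon (from 0.001). The MHC class II median became 1.09 for the high fat diet in brown fat (from 0.81), −0.56 for the extract in brown fat (from −0.45) and −0.47 for the extract in ileum (from −0.57).

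With the authors' values, which scale each array to another point, these moved. The FXR target and bile acid transport median became 0.19 for the high fat diet in ileum (from 0.29). The ceramide synthesis median became 0.22 for the high fat diet in brown fat (from −0.062), −0.036 for the extract in brown fat (from 0.064) and −0.061 for the high fat diet in ileum (from 0.042). The lipogenesis median became −0.86 for the high fat diet in brown fat (from −1.14) and −0.090 for the extract in brown fat (from 0.010). The cholesterol synthesis median became −0.033 for the high fat diet in ileum (from 0.069). The fatty acid oxidation median became −0.051 for the high fat diet in brown fat (from −0.33), 0.22 for the extract in brown fat (from 0.32) and 0.45 for the high fat diet in ileum (from 0.55). The thermogenic median became −0.021 for the high fat diet in brown fat (from −0.30) and 0.17 for the extract in brown fat (from 0.27). The white adipocyte median became −0.008 for the high fat diet in brown fat (from −0.29) and 0.058 for the extract in brown fat (from 0.16). The macrophage median became 1.88 for the high fat diet in brown fat (from 1.59), −1.02 for the extract in brown fat (from −0.92) and −0.16 for the high fat diet in ileum (from −0.060). The inflammatory mediator median became 1.15 for the high fat diet in brown fat (from 0.87), −0.66 for the extract in brown fat (from −0.56) and −0.85 for the high fat diet in ileum (from −0.74). The MHC class II median became 1.09 for the high fat diet in brown fat (from 0.81), −0.55 for the extract in brown fat (from −0.45) and −0.35 for the high fat diet in ileum (from −0.25). The antimicrobial and stress median became −0.65 for the high fat diet in ileum (from −0.54).

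Counting only genes well above background on both arrays leaves out genes with a bound. Totals became 206 for porphyran, 225 for the extract and 93 for extract against porphyran in liver and 343 for extract against porphyran in mesenteric fat. The next totals are listed for high fat diet, porphyran, extract and extract against porphyran. They were 856, 235, 415 and 140 in brown fat and 420, 256, 151 and 294 in ileum. They were 217 for the high fat diet, 103 for the extract and 343 for extract against porphyran in colon. In at least 4 tissues it gave 4 higher for the high fat diet (from 9), 1 lower for porphyran (from 2) and 2 lower for the extract (from 4). Returned genes numbered 143 in liver, 68 in brown fat and 63 in colon with porphyran and 129 in liver, 204 in brown fat, 33 in ileum and 26 in colon with the extract. Genes changed alike were 102 in liver, 109 in brown fat, 36 in ileum and 27 in colon. The macrophage median became 1.49 for the high fat diet in brown fat (from 1.59). The inflammatory mediator median became 0.36 for the high fat diet in liver (from 0.51), −0.14 for the high fat diet in mesenteric fat (from −0.26), −0.71 for the extract in brown fat (from −0.56) and −0.62 for the high fat diet in ileum (from −0.74).

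With no filter on dim probes, signals near background enter the counts. Totals became 2084 for the high fat diet, 1644 for porphyran, 1498 for the extract and 1332 for extract against porphyran in liver. In mesenteric and brown fat they were 2355 for porphyran, 2171 for the extract and 1289 for extract against porphyran in mesenteric fat, and 2410 for the high fat diet, 1718 for porphyran, 1965 for the extract and 2147 for extract against porphyran in brown fat. The gut counts are listed for high fat diet, porphyran, extract and extract against porphyran. They were 1771, 1207, 1175 and 1345 in ileum and 1260, 1367, 1006 and 1383 in colon. In at least 4 tissues it gave 15 lower for the high fat diet (from 4), 8 higher for porphyran (from 0), 4 lower for porphyran (from 2), 13 higher for the extract (from 0), 10 lower for the extract (from 4), 2 higher for extract against porphyran (from 0) and 1 lower for extract against porphyran (from 0). Returned genes numbered 841 in liver, 748 in brown fat, 501 in ileum and 462 in colon with porphyran. With the extract they were 678 in liver, 736 in brown fat, 470 in ileum and 339 in colon, and genes changed alike 610 in liver, 1378 in mesenteric fat, 619 in brown fat, 334 in ileum and 337 in colon. Correlations across genes became −0.583 for porphyran in liver (from −0.697), −0.482 for the extract in liver (from −0.636), 0.494 for both supplements in liver (from 0.715), −0.738 for the extract in mesenteric fat (from −0.841), −0.445 for the extract in brown fat (from −0.683), 0.446 for both supplements in brown fat (from 0.751) and −0.461 for porphyran in ileum (from −0.717). The ceramide synthesis median became 0.30 for the high fat diet in mesenteric fat (from 0.42) and −0.062 for the high fat diet in ileum (from 0.042). The lipogenesis median became −0.79 for the high fat diet in mesenteric fat (from −0.94). The macrophage median became 1.70 for the high fat diet in brown fat (from 1.59). The inflammatory mediator median became 0.065 for the extract in mesenteric fat (from 0.18), 0.68 for the high fat diet in brown fat (from 0.87), −0.43 for the extract in brown fat (from −0.56), −0.62 for the high fat diet in ileum (from −0.74) and 0.56 for porphyran in ileum (from 0.73).

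Averaging all probes of a gene gave 1 lower for porphyran (from 2) in at least 4 tissues. The ceramide synthesis median became 0.31 for the high fat diet in mesenteric fat (from 0.42). The macrophage median became 1.41 for the high fat diet in brown fat (from 1.59) and −0.15 for porphyran in colon (from −0.28). The inflammatory mediator median became −0.65 for the extract in brown fat (from −0.56).

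Leaving out genes typical of other tissues, the alternative chosen after seeing the data, gave 441 for the high fat diet, 181 for porphyran and 293 for the extract in liver. It gave 825 for the extract and 214 for extract against porphyran in mesenteric fat, 425 for the extract in brown fat, 424 for the high fat diet in ileum and 176 for the high fat diet in colon.

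Signal over background limits which genes can be compared: between 13729 and 16806 genes were well above background per array. The slide of the liver arrays held control and high fat diet arrays of liver and mesenteric fat, and a difference within a slide stays as it is when the slide's mean is subtracted. For the comparisons across slides, in mesenteric fat and brown fat, the slides held other mixes of tissues, so the slide alternative was not run.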

Other observations

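Immediate early genes, which cells switch on soon after a stimulus, moved both ways on the high fat diet. In liver 4 of 20 members rose and 0 fell, with Atf3 up 3.40-fold, Fos 2.70-fold and Jun 2.44-fold. In mesenteric fat 5 of 20 members rose and 1 fell, with Atf3 up 12.8-fold and Fos 6.29-fold. In brown fat 2 of 20 members rose and 3 fell: Atf3 rose 2.95-fold, while Nr4a1 and Nr4a2 fell 2.58-fold and 2.75-fold. With porphyran, Atf3 and Fos of mesenteric fat fell 6.28-fold and 4.63-fold, and with the extract 5.64-fold and 3.91-fold. In brown fat Fos fell 2.80-fold with the extract. In liver Irs2, which carries the insulin signal, fell 2.14-fold on the high fat diet.

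Fatty acid oxidation genes of ileum had a median of 0.55 on the high fat diet, −0.56 with porphyran and −0.38 with the extract. Ppara, the receptor that drives them, fell 2.12-fold with porphyran, and Pdk4 fell 2.22-fold with the extract. The incretin gene Gip rose 2.23-fold in ileum on the high fat diet, and the neuropeptide gene Tac1 fell 2.97-fold. The circadian clock list had a median of 0.46 there, and −0.51 with porphyran in colon. The mast cell genes Cpa3 and Mcpt4, higher in colon on the high fat diet, fell 2.62-fold and 2.48-fold with porphyran.

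Of the tests that follow, those on macrophage and endothelial markers, on the extract pool of mesenteric fat, on the 50 brightest liver genes and on the muscle layer were chosen after the result was seen. So was the condition that a quartile of the distal gut genes passes the bound as well as their median.

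Pancreas and lymphocyte genes of mesenteric fat were lower on the high fat diet array than on the other 3, and pieces of pancreas and lymph node in the fat of the other pools are candidate explanations. The 6 islet hormone genes, 2 of them also in another list and 3 above background on the high fat diet array, had a median of 2.85 log2 for porphyran against the high fat diet and −4.19 for the high fat diet against control, although Sst went the other way at 1.14. With the extract, 5 of them had a median of 1.002, with Gcg and Sst the other way at −0.80 and −0.51. The islet genes thus leave pancreas in that pool open. The exocrine pancreas genes, which make up the pattern itself, rose there in 20 of 20 cases (median 4.87). The 4 measured genes of lymph node vessels and stroma, all above background on that array, had a median of −3.14 on the high fat diet, 2.22 with porphyran and 2.11 with the extract. A lower share of every cell type other than adipocytes is argued against by the endothelial and macrophage markers, whose medians on the high fat diet were 0.81 and 1.16, and what part of the immune changes came from the diets was not tested.

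Liver genes were higher on 1 array each of brown fat, colon and ileum, and traces of liver RNA in those pools may be the source. Of the genes at least 64-fold brighter in liver than on the control diet array of brown fat or the high fat diet array of colon or ileum, a choice that favours low values on those arrays, 51.2% of 455 on the high fat diet array of brown fat lay above each of the other 3 arrays, as did 76.2% of 391 on the control diet array of colon and 62.6% of 366 on that of ileum, and none reached the share set beforehand. Among the 50 brightest the shares were 88.0%, 92.0% and 86.0%, of which only that of colon reached the level asked for, set after the result was seen, with median excesses of 0.0899%, 0.198% and 0.0596% of the liver level. Alb was at 1.24, 2.55 and 1.12 log2 on the brown fat, colon and ileum arrays and 10.33 in liver. Other arrays reached at most −0.93 in brown fat and −1.99 in colon, and none in ileum was well above background. Apoa1 and Serpina1c on the ileum array lay below another ileum array, at 5.58 against 6.56 and 3.57 against 4.03. In all 3 tissues, liver RNA and expression in the tissue itself cannot be told apart. The shares of all such genes lay between the bounds set and cannot decide. At median excesses of 0.0361% to 0.0989% of the liver level, genes 64-fold dimmer than in liver barely rise. No biological explanation was tested.

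On the porphyran array of colon Hoxd10, Hoxd11 and Hoxd12 were lower and Reg3 genes higher, and a more proximal stretch of colon in that pool might give both. The 7 measured distal gut genes not looked at before had a median of −0.14, above the bound set beforehand against this explanation, but their lower quartile of −0.93 lay below it: Hoxd9 and Hoxd13, of the same gene cluster, were at −1.55 and −1.63, and the other 5 lay between −0.31 and 0.46 with a median of −0.04. The genes outside that cluster thus did not fall and those in it did, and how either differ along the colon was not measured here. Position along the colon and an effect of porphyran therefore cannot be told apart. Slc9a3 and Isx, which rose on the same array, were not part of this test. A lower share of muscle layer stays open too: the smooth muscle list had a median of −0.47 with 18 of 18 members below 0, and the 3 Hoxd genes, picked as low ones, lay at −1.80 relative to it. An effect of porphyran itself was not tested, as 1 pool stood for each diet.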
